A study of Homo sapiens with 3 samples.

How the data were processed

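Total RNA was sequenced from 3 libraries of cells sorted from kidney organoids on day 25 of differentiation. The organoids were grown from the human induced pluripotent stem cell line CRL1502 (clone C32). Per the labels' protocols, the cells received the GSK3 inhibitor CHIR99021 at 8 µM for 4 days and then FGF9 at 200 ng/mL with heparin at 1 µg/mL for 3 days. They were then pelleted on a membrane, given 5 µM CHIR99021 for 1 h, kept in FGF9 and heparin for 5 days and left in basal medium for a further 12 days. Organoids were dissociated for 10 minutes at 37 °C, and cells that bound LTL, the Lotus tetragonolobus lectin used as a marker of proximal tubule, were taken by magnetic sorting. The libraries were made with a stranded total RNA kit after depletion of ribosomal RNA, per the labels' protocols. All 3 libraries formed 1 group, with no unsorted, negative or treated sample beside it, so no difference between groups was tested. Nothing in the labels says whether the replicates were separate cultures, so an SD over libraries measures the spread between these 3 libraries alone. SDs over members of a list and tests across genes describe genes within these libraries.

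Both count tables were used. The first holds raw counts per gene symbol, deposited for the hg19 build as whole numbers without scaling, per the file headers and the values. It has 42785 rows and was the main table, as fixed before the data were examined. The second holds estimated counts per Ensembl gene, deposited for the hg38 build without scaling, per the file headers. It has 38663 rows, and 49.6% of its values were whole within 1e-06. Both tables also list other values per row, a gene length in the first and an average length in the second, as the authors deposited them. The submitters' processing notes name STAR 2.4.0h1, featureCounts 1.4.6 and Salmon 0.8.2 without saying which tool made which table. The annotation, the treatment of reads with several positions and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies may therefore have been shared or dropped.

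Counts per 1000000 counts (CPM) were computed on each library's total count. Totals of the main table were 19994338, 24825239 and 23036883 counts in libraries 1, 2 and 3. A count of 0 allowed up to 3 counts, which was 0.121 to 0.150 CPM, and this floor covers counting error only. Log2 values used a pseudocount of 0.5 CPM. A gene was called detected at 1 CPM or more in each of the 3 libraries. Effective library sizes came from TMM in edgeR 4.0.16 under R 4.3.3, and alternatively from DESeq2 1.42.0 size factors. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. CPM is not corrected for gene length, and a length-corrected version was an alternative. The Ensembl identifiers were given symbols from GENCODE 29, which named 34425 of them. The 4238 identifiers without a symbol held 1.96% of the estimated counts. The tables shared 19717 symbols, which held 47.5% of the counts of the main table.

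Before the data were examined, 13 lists of cell type markers and 13 lists of functional genes were fixed, together with the rule for named genes. The tests and alternatives were also fixed then, apart from those named below as added later. The proximal tubule list was compared with each of the 12 other cell type lists by a two-sided permutation test across genes with 100000 resamples, with Benjamini-Hochberg adjustment over the 12 tests. The test statistic was the difference in mean log2(CPM + 0.5), with gene values averaged over the libraries. Genes are not independent replicates, so this test describes the lists and not a population of cultures. Counts of each gene with a mean of 10 or more were tested against Poisson sampling by chi-square at the TMM sizes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Common and tagwise dispersions came from edgeR with an intercept alone. Movement of a list between libraries was tested by two-sided permutation of the libraries within genes, on members with a mean of 1 TMM-scaled CPM or more, and by exact enumeration for lists of 7 or fewer such members. Each list's range was also placed among 10000 random lists of the same size matched on mean expression. The tables were compared by counting genes whose CPM differed 2-fold or more in the same direction in each library, among genes with a mean of 1 CPM in either table. Estimated counts were rounded for the count models.

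The named genes were the 10 most abundant outside the mitochondrial genome, up to 4 highest and 2 lowest members of every list, and a fixed set of kidney genes. That set included HNF4A, LRP2, CUBN, AQP1, SLC34A1, SLC5A1, SLC5A2, SLC22A6, SLC22A8, SLC22A2, ABCB1, ABCG2, NPHS1, UMOD, SLC12A1, GATA3, SIX2, COL1A1 and PECAM1. They also included the 10 genes of largest tagwise dispersion at 10 CPM or more past the threshold, and the 5 genes of largest difference between the tables in each direction at 10 CPM or more. Text names a part of the genes that this rule takes. Genes of the Y chromosome, genes shared by both sex chromosomes and XIST were left out of every result on single genes.

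The Poisson test, the comparison of lists and the test of list movement were tested on simulated data. For the Poisson test, counts were drawn by Poisson sampling for the real genes at the real library sizes, with 200 genes changed in 1 library. Its rate for unchanged genes therefore covers counting noise only. Over 17979 genes, the Poisson test called 65.7% of the 1.5-fold, 85.1% of the 2-fold and 100% of the 4-fold changes, and 0.062% of the unchanged genes. The permutation test between lists called 4.0% of simulated pairs with no difference and 94.5% of pairs that differed by 3 log2 units. The test of movement between libraries called 5.2% of 2000 simulated lists without movement and 99.9% of those moved by 1 log2 unit in 1 library. Both list tests were simulated with normal values drawn independently for each gene. Their rates therefore do not cover real lists, whose genes can vary together.

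The alternatives were each library left out in turn, the other table, other library sizes, length correction, other pseudocounts, the median in place of the mean, and other filters and thresholds. Leaving out libraries in the test of list movement was added after seeing the data. Sequence matches between noncoding RNAs and transcripts of GENCODE 29 were found with blastn of BLAST 2.17.0.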

Results

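Gene expression was measured by RNA sequencing of total RNA in cells sorted with the lectin LTL from day 25 human kidney organoids. There was 1 group of 3 libraries, here called libraries 1, 2 and 3. The main table held 19994338, 24825239 and 23036883 counts for them. Values below are means over the 3 libraries with the SD (n = 3), in counts per 1000000 counts (CPM), unless a single library is named. Intervals and floors from counts cover counting error only, and 3 counts corresponded to 0.121 to 0.150 CPM.

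The first question was which genes the sorted cells expressed. MT-RNR1 and MT-RNR2, the ribosomal RNAs of mitochondria, took 39.99% ± 0.783 of all counts. RN7SK, a small nuclear RNA that restrains transcription elongation, took 3.79% ± 0.543. RMRP, RPPH1, RN7SL1 and RN7SL2 together took 2.82% ± 0.390, and all genes annotated as snRNA took 0.0384% ± 0.00543. Nuclear protein-coding genes took 46.4% ± 0.537. Among these, EEF1A1, an elongation factor of translation, stood at 3674 ± 399 CPM, the ferritin light chain FTL at 1328 ± 328 CPM and the actin ACTG1 at 1247 ± 58.4 CPM. MALAT1, a nuclear long noncoding RNA, stood at 5822 ± 1801 CPM. The cytoplasmic ribosomal RNAs RNA28S5 and RNA18S5 differed between the libraries, with 3.57% of counts in library 1, 0.939% in library 2 and 0.475% in library 3. At 1 CPM or more in each of the 3 libraries, 14292 genes were detected, of which 12024 were among the 18327 nuclear protein-coding genes of the table. Single libraries had 15048, 15033 and 15542 genes at that level.

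The labels call the sorted cells proximal tubule, so the proximal tubule list was set against lists of other cell types. Genes of protein uptake by the proximal tubule were among its highest members, with CUBN (cubilin) at 573 ± 211 CPM and LRP2 (megalin) at 477 ± 132 CPM. The bicarbonate transporter SLC4A4 stood at 241 ± 28.2 CPM, and GATM, an enzyme of creatine synthesis, at 132 ± 53.4 CPM. The transcription factor HNF4A stood at 109 ± 37.6 CPM. Of the 26 members, 20 were at 1 CPM or more in each library and 14 had a mean of 10 CPM or more. The water channel AQP1 stood at 24.0 ± 17.3 CPM and the phosphate transporter SLC34A1 at 22.4 ± 22.9 CPM. The lowest members were the glucose transporter SLC5A2 at 1.09 ± 0.526 CPM and the organic anion transporter SLC22A6 at 1.01 ± 1.26 CPM. In GENCODE 29 on GRCh38, LRP2 lies on chromosome 2 from 169127109 to 169362685, CUBN on chromosome 10 from 16823966 to 17129817 and SLC34A1 on chromosome 5 from 177379235 to 177398848.

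Genes of other nephron segments were also expressed. SLC12A1, the salt transporter of the thick ascending limb of the loop of Henle, stood at 962 ± 178 CPM, above LRP2 and CUBN in the mean. SLC12A1 lies on chromosome 15 from 48178438 to 48304078 in GENCODE 29 on GRCh38. The potassium channel KCNJ1 stood at 43.4 ± 10.4 CPM and the tight junction gene CLDN16 at 23.2 ± 11.4 CPM, and 11 of the 14 loop members were at 1 CPM in each library. UMOD, which encodes the main protein of normal urine, had a mean of 0.0623 CPM, under the floor. Among podocyte genes, PODXL stood at 180 ± 150 CPM, PTPRO at 68.3 ± 58.8 CPM and NPHS1 (nephrin) at 49.6 ± 28.3 CPM, and 15 of 16 members were at 1 CPM in each library. Among the cell type lists, that of the early nephron epithelium had the highest mean log2(CPM + 0.5) over the 3 libraries (4.99), though in library 3 stroma (5.30) and podocyte (5.10) lay above it (5.04). Its members included the Notch ligand JAG1 at 442 ± 46.2 CPM, the cadherin CDH6 at 185 ± 81.4 CPM and PAX8 at 173 ± 8.45 CPM. Only 4 of 20 members of the distal tubule and collecting duct list were at 1 CPM in each library, led by TFAP2B at 22.4 ± 2.92 CPM, with GATA3 at 0.883 ± 0.521 CPM. Of the nephron progenitor list, SALL1 stood at 47.8 ± 7.48 CPM and SIX2, a factor of self-renewing progenitors, at 0.0311 CPM, under the floor.

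Genes of cell types outside the nephron were mostly low, apart from stroma. The collagens COL1A2, COL3A1 and COL1A1 stood at 408 ± 261, 248 ± 354 and 95.6 ± 125 CPM, and 11 of 15 stromal genes were at 1 CPM in each library. The endothelial receptor KDR stood at 4.58 ± 7.21 CPM, and 3 of 14 measured endothelial genes and 0 of 12 immune genes were at 1 CPM in each library. The immune gene AIF1, with 0 counts, lies in a stretch of chromosome 6 where the main table was low. In otherwise low lists, single genes had high CPM, a measure that is not corrected for gene length. NEFL, a neurofilament gene, stood at 72.2 ± 21.9 CPM, the muscle gene TTN at 83.9 ± 8.86 CPM, the endothelin receptor EDNRB at 136 ± 56.2 CPM, MITF at 101 ± 17.1 CPM and DPPA4, a gene of pluripotent cells, at 77.7 ± 19.2 CPM. Others of the same lists were near 0, among them ELAVL4 at 0.0134 CPM, SOX10 at 0.226 ± 0.0699 CPM and L1TD1 at 0.209 ± 0.134 CPM.

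**Figure D1:**
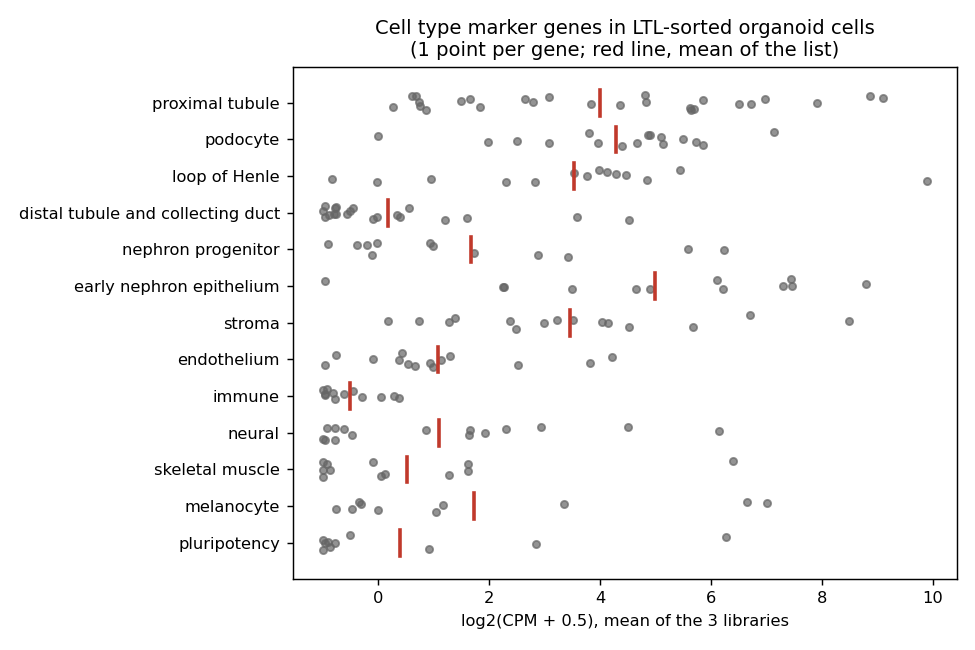
Each point is 1 gene of a cell type list at its mean log2(CPM + 0.5) over the 3 libraries, and the red line is the mean of the list. The proximal tubule mean lies at 4.00, below those of the early nephron epithelium at 4.99 and of podocytes at 4.29. The loop of Henle mean lies at 3.54 and the immune mean at -0.51.

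In the mean over members of log2(CPM + 0.5), the proximal tubule list lay above 7 of the 12 other lists past the threshold of the two-sided permutation test. The difference was 3.82 log2 units against distal tubule and collecting duct (adjusted permutation p = 0.00018), 4.51 against immune (adjusted permutation p = 0.00018) and 3.49 against skeletal muscle (adjusted permutation p = 0.00204). Against pluripotency it was 3.61 (adjusted permutation p = 0.00266), against endothelium 2.93 (adjusted permutation p = 0.00252), against neural 2.91 (adjusted permutation p = 0.00268) and against nephron progenitor 2.32 (adjusted permutation p = 0.0288). Each of these 7 differences was above 0 in 3 of 3 libraries. Against pluripotency the difference was smaller with the hg38 table, at 2.81 (adjusted permutation p = 0.0154). The difference of 2.27 against melanocyte did not pass (adjusted permutation p = 0.0548), though it did without replicate 2 (2.33) and without replicate 3 (2.51). The proximal tubule list was not distinguished from the loop of Henle (0.47, adjusted permutation p = 0.659), podocyte (-0.28, adjusted permutation p = 0.711), early nephron epithelium (-0.99, adjusted permutation p = 0.417) or stroma (0.56, adjusted permutation p = 0.616). The stromal and podocyte differences turned with the library. Against stroma the difference was 1.99 in library 1, 1.24 in library 2 and -1.57 in library 3, and against podocyte it was 0.42, 0.09 and -1.37. The podocyte difference was 0.26 without replicate 3, and the stromal one was -0.16 without replicate 1. When lists kept only members with a mean of 1 CPM or more, 0 of the 12 differences passed, and the nephron progenitor difference also failed without replicate 1 (1.82, adjusted permutation p = 0.103).

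The functional lists described which genes of proximal tubule tasks had transcripts in these cells. At 1 CPM or more in each library, 12024 of the 18327 nuclear protein-coding genes were detected. The list counts were not tested against that share. All 12 genes of protein endocytosis were at 1 CPM in each library, with the chloride transporter CLCN5 at 385 ± 63.5 CPM and the motor MYO6 at 209 ± 17.7 CPM beside CUBN and LRP2. Of the brush border list, 15 of 18 genes were at that level, led by the peptidases DPP4 at 470 ± 94.3 CPM and MME at 178 ± 21.5 CPM and by the linker EZR at 378 ± 30.5 CPM. Both meprin genes were low, with MEP1B at 0.473 ± 0.195 CPM and 0 counts for MEP1A. Of the solute reabsorption list, 19 of 24 genes were at 1 CPM in each library, among them SLC3A1 at 94.3 ± 36.4 CPM and SLC5A8 at 78.8 ± 46.7 CPM, while the glucose transporter SLC5A1 stood at 0.608 ± 0.2999 CPM. Of the organic ion and drug transporters, 11 of 16 were at that level, and 7 at 5 CPM. The efflux pumps ABCC4, ABCC2 and ABCB1 stood at 77.3 ± 15.1, 37.5 ± 20.5 and 34.1 ± 2.62 CPM and the carnitine transporter SLC22A5 at 57.8 ± 11.8 CPM. The uptake transporters SLC22A2 and SLC22A8 stood at 2.41 ± 0.887 and 1.21 ± 0.751 CPM, and the efflux pump ABCG2 at 0.724 ± 0.804 CPM.

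Lists of metabolism differed in how many members were detected. All 12 genes of fatty acid oxidation and all 13 of glycolysis were at 1 CPM in each library, with ACADVL at 251 ± 13.5 CPM, HADHA at 179 ± 9.49 CPM, ENO1 at 447 ± 65.3 CPM and GAPDH at 421 ± 33.4 CPM. Of gluconeogenesis and ammoniagenesis, 9 of 10 genes were at that level, and G6PC stood at 2.78 ± 2.06 CPM. Of xenobiotic and vitamin D metabolism, 4 of 12 genes were at that level, namely GSTP1 at 301 ± 20.97 CPM, UGT2B7 at 103 ± 11.6 CPM, SULT1C2 at 34.6 ± 2.44 CPM and CYP3A5 at 17.5 ± 12.8 CPM. The cytochrome CYP4A11 stood at 0.0612 CPM and CYP24A1 at 0.0333 CPM, both under the floor.

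Genes of injury, dissociation, growth and early development were also present. Of the injury list, 9 of 11 measured genes were at 1 CPM in each library, with VIM at 229 ± 99.2 CPM, CLU at 174 ± 15.8 CPM, KRT8 at 173 ± 3.44 CPM and LCN2 at 0.135 ± 0.0484 CPM. Of the immediate early list, 12 of 14 were at that level, led by FOS at 267 ± 51.0 CPM, JUN at 197 ± 19.6 CPM and EGR1 at 122 ± 9.84 CPM. IER3 and HSPA1A, in the same stretch of chromosome 6 as AIF1, had 0 counts. Of the proliferation list, 13 of 16 were at 1 CPM in each library and 5 at 5 CPM, with MCM2 at 33.4 ± 5.67 CPM and TOP2A at 23.7 ± 21.996 CPM. The fetal list had 9 of 10 at 1 CPM in each library, with HMGA2 at 148 ± 38.9 CPM, MEST at 132 ± 24.4 CPM and IGF2BP1 at 101 ± 14.7 CPM, and LIN28B at 7.01 ± 2.14 CPM. The fucosylation list holds fucosyltransferases and other genes of fucosylation, chosen because LTL binds fucose-bearing glycans. Of these, 13 of 16 were at 1 CPM in each library, led by the fucosyltransferases FUT9 at 33.1 ± 10.3 CPM and FUT4 at 27.7 ± 4.22 CPM. Which of them act on the glycans that LTL binds was not tested. Across all 13 functional lists, memberships at 1 CPM in each library added to 151.

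The libraries were then compared with each other, to separate their spread from counting noise. The 10 genes of largest dispersion were all highest in library 3. COL3A1 stood at 29.2, 59.1 and 641 TMM-scaled CPM in libraries 1, 2 and 3, POSTN at 4.52, 3.45 and 73.3, ACTA2 at 1.52, 1.54 and 33.5, and IGFBP5 at 9.75, 17.9 and 152. The others were TNC, COL21A1, the choline transporter SLC5A7, EDNRA, MMP2 and TGFBI. Some transporters varied in another way, with SLC34A1 at 48.4, 16.5 and 3.01 TMM-scaled CPM and SLC22A6 at 2.49, 0.447 and 0.127. ABCB1, at 36.4, 31.4 and 34.5, differed 1.16-fold between its highest and lowest library. Counts departed from Poisson sampling for 9673 of 17993 genes by a chi-square test with Benjamini-Hochberg adjustment. In pairs of libraries, 28.6% of genes departed between libraries 1 and 2, 39.9% between 1 and 3 and 41.3% between 2 and 3. The common biological coefficient of variation from edgeR was 0.253, and 0.167 without replicate 3, when 5052 genes departed. Among 15323 genes with a mean of 1 TMM-scaled CPM or more, 578 were 2-fold or more above both others in library 3, against 74 in library 1 and 24 in library 2. Genes 2-fold or more below both others numbered 65, 68 and 80 in libraries 3, 1 and 2.

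Genes of the same list moved together between libraries. The stromal list stood highest in library 3, at 1.85 log2 units above its mean over the libraries, against -0.83 in library 1 and -1.02 in library 2, and all 14 members tested were highest there. The endothelial list (1.28 in library 3), the podocyte list (0.78) and the proliferation list (0.80) were also highest in library 3. TOP2A stood at 10.2, 12.0 and 47.9 TMM-scaled CPM, KDR at 0.152, 0.691 and 12.6, and PODXL at 132, 61.4 and 339. The proximal tubule list was highest in library 1, at 0.62 against -0.32 in library 2 and -0.30 in library 3, with 24 of 26 members highest there. Library 1 also had the largest share of RNA28S5 and RNA18S5, at 3.57% of counts against 0.939% and 0.475%. Organic ion and drug transporters (0.56 in library 1), gluconeogenesis and ammoniagenesis (0.50), solute reabsorption (0.45) and brush border (0.36) were also highest in library 1. Each of these lists shares members with the proximal tubule list, such as SLC34A1 and SLC22A6, so their movements are not separate observations. LRP2 stood at 587, 330 and 512 TMM-scaled CPM, and AQP1 at 44.0, 9.87 and 18.4. Against these lists, the fetal list was lowest in library 1, at -0.46 against 0.10 in library 2 and 0.36 in library 3, and glycolysis at -0.18 against 0.11 and 0.07. Endocytosis (0.20) and fatty acid oxidation (0.12) were highest in library 1. The loop of Henle list showed no movement past the test, with -0.03, 0.05 and -0.02, nor did immediate early genes or fucosylation.

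Of the 25 lists with 3 or more members tested, 13 moved past the threshold of the permutation within genes, against 4 without replicate 1 and 8 without replicate 3. With all members kept, whatever their expression, 16 lists passed. Nephron progenitor, neural and immune were then added (adjusted permutation p = 0.00708, 0.0140 and 0.00242). For the stromal, podocyte and proximal tubule lists the permutation p was 1e-05, the smallest that 100000 permutations can give, and the adjusted permutation p was 4e-05. The adjusted permutation p was 0.00057 for endothelium, 6.5e-05 for proliferation and for organic ion and drug transporters, 0.000325 for solute reabsorption, 0.000303 for brush border and 0.000832 for gluconeogenesis and ammoniagenesis. Weaker movements passed for glycolysis (adjusted permutation p = 0.00561), the fetal list (0.0127), fatty acid oxidation (0.0337) and endocytosis (0.0386), of which the last 2 did not pass on total counts (adjusted permutation p = 0.118 and 0.0787). Among 10000 random lists matched on mean expression, the range of fatty acid oxidation lay at percentile 93.5, glycolysis at 97.7, endocytosis at 97.8 and the other 10 lists at 99.97 or above. Without replicate 3, the ranges of stroma (0.11), endothelium (0.25) and proliferation (0.09) no longer passed. Without replicate 1, neither did those of proximal tubule (0.07), organic ion and drug transporters (0.07), solute reabsorption (0.10), brush border (0.03), gluconeogenesis and ammoniagenesis (0.28), glycolysis (0.04) or the fetal list (0.26). Endocytosis did not pass with any of the 3 libraries left out (0.01 without replicate 1, 0.30 without replicate 2 and 0.31 without replicate 3), and fatty acid oxidation did not pass without replicate 1 or without replicate 3 (both 0.12).

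**Figure D2:**
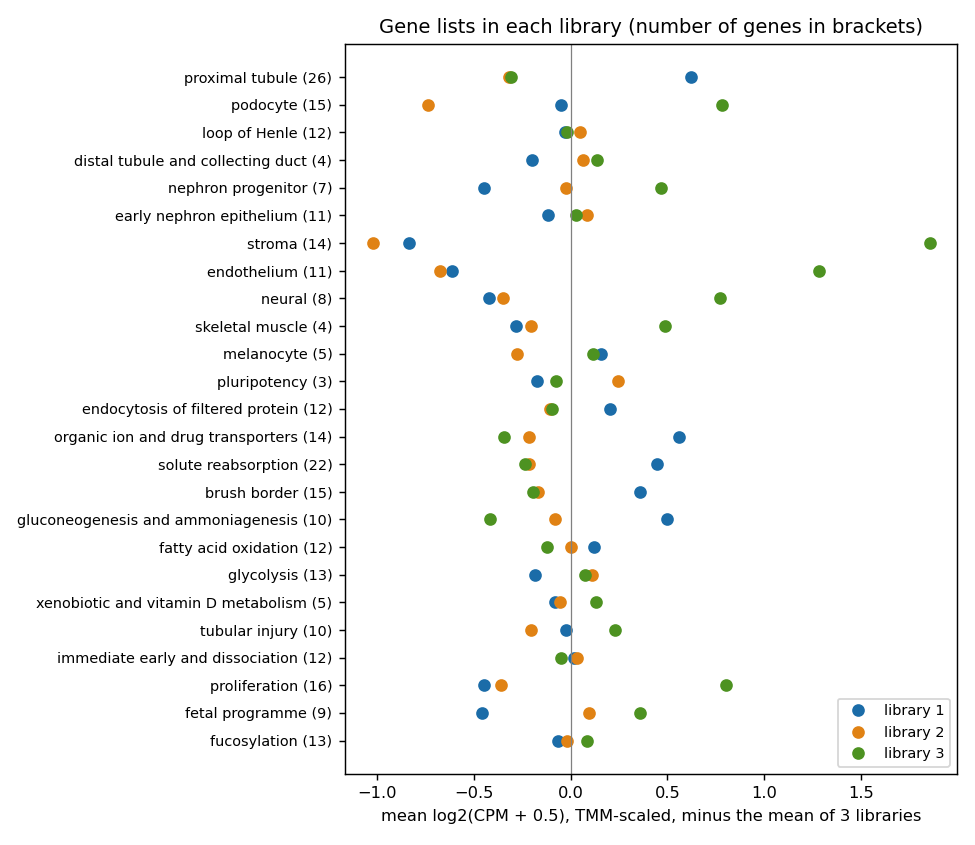
Each point is the mean log2(CPM + 0.5) of a list in 1 library, TMM-scaled, minus the mean of the 3 libraries, and colours mark the libraries. Stroma in library 3 lies at 1.85 and the proximal tubule list in library 1 at 0.62, while the 3 points of the loop of Henle lie between -0.03 and 0.05.

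The same libraries were counted against hg19 and hg38, and both tables were compared gene by gene. The kidney genes given next differed by 0.31 to 0.57 log2 units. LRP2 stood at 477 ± 132 CPM in the hg19 table and 598 ± 166 CPM in the hg38 table, a log2 difference of 0.33 ± 0.01, and SLC12A1 at 962 ± 178 and 1424 ± 259 CPM, a difference of 0.57 ± 0.03. The differences of CUBN, HNF4A, SLC34A1, NPHS1 and COL1A1 lay between 0.31 and 0.37. The median over 14088 genes was 0.40 log2 units, and -0.05 after TMM scaling over the matched genes. The genes with the largest excess in the hg38 table were FAM83A (0.0435 against 13876 CPM), MTRNR2L1 (0.614 against 22395 CPM), PLCG2 (5.57 against 35563 CPM), MTRNR2L6 (0.0446 against 2854 CPM) and MTRNR2L8 (12.9 against 43884 CPM). Lower in the hg38 table were PHRF1 (45.3 CPM in the hg19 table), TUBB (36.2 CPM), MTRNR2L9 (31.1 CPM) and MRPL45 (19.4 CPM), whose hg38 means lay under the level of 3 estimated counts, which was 0.151 to 0.188 CPM. NDUFA6 followed, at 49.3 CPM in the hg19 table and 1.32 CPM in the hg38 table. The hg38 values cover only identifiers that received a symbol, and those without one held 1.96% of the estimated counts. Whether identifiers without a symbol hold counts of these lower genes was not tested.

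In all, 1728 genes were 2-fold or more higher in the hg38 table in each library and 101 were lower, so 94.5% of these genes were higher. With TMM scaling over matched genes, 1273 were higher and 217 lower, or 85.4% higher. Genes on chromosome 6 between 28903002 and 33457548 on GRCh38, a stretch that spans the major histocompatibility complex, stood apart. The median difference of the 89 genes compared there was 2.97 log2 units, and 72 were 2-fold higher in the hg38 table. For 645 other genes of chromosome 6 the median was 0.36. The ribosomal protein gene RPS18, chosen after its values were seen, stood at 0.0468 CPM in the hg19 table and 147 ± 12.1 CPM in the hg38 table. Levels of single genes there, and of FAM83A, PLCG2, PHRF1, TUBB and the named MTRNR2L genes, depended on the table as matched here by symbol.

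**Figure D3:**
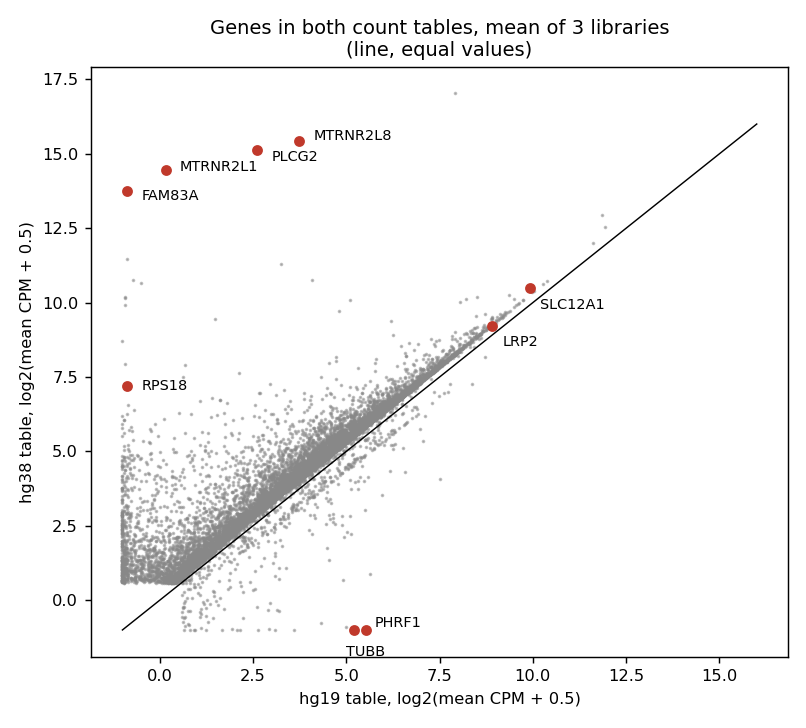
Each grey point is a gene matched between the tables at log2(mean CPM + 0.5) in the hg19 table (x axis) and in the hg38 table (y axis), and named genes are red. LRP2 and SLC12A1 lie near the line of equal values, 0.33 and 0.57 log2 units above it, while FAM83A, PLCG2 and MTRNR2L8 lie far above and PHRF1 and TUBB far below.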

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

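The sequence test, the test on the region of chromosome 6 and the test with a second stromal list were set before their results were seen, and the tests of library size, depth and dilution were chosen only after the pattern they concern was seen.

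CD24, an injury and progenitor marker absent from the hg19 table, stood at 1172 ± 374 CPM (SD, n = 3) in the hg38 table, which the comparisons do not use as their main source. The endothelial gene PECAM1, also absent from the hg19 table, stood there at 3.86 ± 3.90 CPM, with 1.71, 1.51 and 8.36 CPM in libraries 1, 2 and 3.

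Stromal genes were higher in library 3, by 2.78 ± 1.03 log2 units (SD over 14 members) over the mean of libraries 1 and 2. Against unequal library size or dominant transcripts, it was 2.90 with a library size free of mitochondrially encoded and the 10 most abundant genes, and against depth, library 3, whose total lies between the others, exceeded the higher of them by 2.69 ± 1.17. Cells of another type remain a candidate explanation, since a second list of 16 stromal genes not used before had a median of 1.12 (interquartile range 0.47 to 1.51) and 15 of the 16 were highest in library 3. Its abundant genes differed less, with VCAN at 603, 717 and 914 TMM-scaled CPM and COL6A1 at 222, 247 and 275, but 9 of the 16 were already at 10 CPM or more in both other libraries. LTL sorting should remove stromal cells, expression of these genes by LTL-binding cells stays open, and apart from a mixed sample no biological explanation was tested because the design has 1 group.

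Proximal tubule genes were higher in library 1 than in library 2, by 0.94 ± 0.50 log2 units (SD over 26 members), in 25 of 26 members. Dilution by stromal or podocyte cells in library 2 would have raised those lists there, yet library 2 minus library 1 was -0.19 for stroma and -0.69 for podocytes. The same difference was 0.43 for nephron progenitor, 0.26 for distal tubule and collecting duct, 0.20 for early nephron epithelium and 0.08 for loop of Henle. None of these lists moved past the permutation test, and dilution by such cells was not tested. With a library size free of mitochondrially encoded and the 10 most abundant genes the difference was 1.01. As for the stromal list, that size could change the difference little. It shows only that the pattern did not depend on that choice. RNA28S5 and RNA18S5 took 3.57% of counts in library 1 and 0.939% in library 2, and whether a difference in RNA quality or depletion bears on the pattern was not tested. A difference between cultures or in handling stays open, and apart from stromal or podocyte dilution no biological explanation was tested because the design has 1 group.

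Among matched genes with over 500 CPM in the hg38 table, 16 were at least 16-fold higher there than in the hg19 table and took 26.6% of its counts. None lay in the region of the major histocompatibility complex (0%). That share gives the location of these 16 genes only, and alternate contigs of other regions were not examined. Sequence shared with 11 abundant noncoding RNAs, at 90% identity or more over 40 bases or more, was found in 7 of the 16 (43.8%). Among 14072 other genes the share was 10.0% (two-sided Fisher's exact test p = 0.000522). The 7 were of unlike kinds. The longest matches of MTRNR2L12 and MTRNR2L8 (MT-RNR2) and of PLCG2 and RIMBP3C (RN7SK) spanned 237 to 1302 bases. Those of NRSN1, PLLP and WDR74 were to RN7SL1 or RN7SL2 and spanned 95, 49 and 44 bases. RNA28S5 was not among the RNAs searched. The 7 together took 21.9% of the counts, but the share of genes missed the 50% set in advance. Shared sequence therefore remains a candidate explanation that was not settled for FAM83A, MTRNR2L1 and the other 7 genes without a match. Of these, MTRNR2L1, MTRNR2L4, MTRNR2L6 and MTRNR2L10 share a name stem with MTRNR2L12 and MTRNR2L8, which matched MT-RNR2. A missing match at that cutoff does not exclude shared sequence that is shorter or of lower identity.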

How the results depend on the processing

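Every alternative was planned before the data were examined, except leaving out libraries for list movement. Of 214 values under alternatives for the main results, 184 were kept. List differences were kept if their direction and side of the threshold stayed. Counts and the biological coefficient of variation were kept if within 1.5 times the main value. The 214 include descriptive counts and counts that sum up the same list differences. TMM and DESeq2 sizes could change list differences little, since each scales all genes of a library by 1 factor. The share kept is therefore no measure of robustness. Where they did not, the cause was not tested unless named. Keeping only members at 1 CPM or more filters on the expression compared and leaves fewer genes (1 for immune). Then 0 of 12 differences passed, with distal tubule and collecting duct at 1.28, nephron progenitor 0.89, endothelium 2.47, immune 3.62, neural 1.26, skeletal muscle 1.27, pluripotency 0.66 and loop of Henle turned to -0.19. The median gave 3.14 for nephron progenitor, no longer past the threshold, and length correction turned podocyte to 0.10. Melanocyte passed with the other table (2.39), the library size without mitochondrial and top 10 genes (2.52) and a pseudocount of 0.1 (2.77).

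Leaving out each library gave ranges of -0.64 to 0.26 for podocyte (turned without replicate 3), -0.16 to 1.62 for stroma (turned without replicate 1), 1.82 to 2.74 for nephron progenitor (not past the threshold without replicate 1) and 1.98 to 2.51 for melanocyte (past it without replicate 2 or 3). It gave 5052 to 7548 genes past Poisson sampling, a biological coefficient of variation of 0.167 to 0.276, both lowest without replicate 3, and 4 to 12 lists that moved together, with 4 without replicate 1 and 8 without replicate 3. Any count above 0 gave 24150 genes detected. Between the tables, 1.5-fold gave 3377 higher and 194 lower, 4-fold gave 627 and 35, 5 CPM gave 65 lower and TMM 217 lower. Of 190 genes followed, none moved by 1 SD with TMM or DESeq2 sizes, and 104 of 183 did with the other table. With the library size that leaves out mitochondrial and top 10 genes 148 did, but that size raises all genes of a library by 1 factor. No paired analysis was possible because there was 1 group. Depth limits genes near 0.121 to 0.150 CPM, such as UMOD and SIX2.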

Other observations

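No test in this part goes beyond those already given. Marker genes of single segments diverged within the same list. SLC12A1 stood at 971, 1154 and 768 TMM-scaled CPM in libraries 1, 2 and 3, while UMOD, a gene of the same segment, had 0.102, 0 and 0.0847. Within the neural, muscle, melanocyte and pluripotency lists, NEFL, TTN, MITF and DPPA4 stood at 72.2 ± 21.9, 83.9 ± 8.86, 101 ± 17.1 and 77.7 ± 19.2 CPM (SD, n = 3), while MYF5, PAX7 and UTF1 had 0 counts in each library.

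Transcripts of the proximal tubule list spread unevenly between libraries. The ratio of the highest to the lowest library was 16.1 for SLC34A1, against 1.78 for LRP2, 1.99 for CUBN and 2.14 for HNF4A. RNA28S5, a cytoplasmic ribosomal RNA that depletion targets, stood at 36079, 9427 and 4614 TMM-scaled CPM. The nephron progenitor gene SIX2 and the collecting duct gene FOXI1 were at or under the floor, and LYZ, an immune gene, reached 6.69 TMM-scaled CPM in library 3 against 0.102 and 0 in libraries 1 and 2.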
